A study of Homo sapiens with 3 samples.

How the data were processed

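RNA of HK-2 cells was hybridised to 1-colour Agilent arrays, with 1 array each for normal, high phosphate and high sodium medium at 24 h. Per the file headers, the deposited scanner files hold the processed signal as linear intensity, made with Agilent Feature Extraction 10.7.1.1 by subtraction of background with spatial detrending, multiplicative detrending and replacement of low values by a surrogate, with no scaling between arrays. The same files hold the software's error of each spot in intensity, the mean pixel intensity, the median local background intensity and flags, all as deposited. The deposited series matrix holds the processed intensity too: 99.8% of probes on the normal array, 99.7% on the high phosphate array and 99.8% on the high sodium array were within 0.01% of the mean processed signal. Its values were linear and neither centred nor scaled, with medians of 27.3, 24.4 and 26.7.

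Each array had 62976 spots, of which 60901 were not controls and held 58201 probes. Spots marked by the software as non-uniform (4, 10 and 0 on the normal, high phosphate and high sodium arrays) or as outliers of their probe (133, 165 and 154) were left out. The log2 processed signals of the spots of a probe were averaged, and the 75th percentile over non-control probes was subtracted on each array. On the linear scale, the 75th percentile of non-control spots was 430.6, 397.7 and 420.9. Probes well above background by the software's flag numbered 36597, 36518 and 36900, with lowest signals of 10.1, 8.95 and 8.96, so differences between dimmer probes could not be measured. With 1 array per group, the number of arrays limits the precision and no p-value, SD or SE between replicates can be given. The spot error is the software's, carried to the log2 difference, with a median over genes of 0.21.

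Probes were named from the supplied table of RefSeq names by accession (31104), current symbol (3366) or an older symbol of 1 gene (485). The other 23246 kept the name in the file, among them 11 whose older symbol belongs to a gene on another chromosome. This gave 43411 gene names. Probe positions are those of the file headers on hg19, and the sources used here did not give the exon or transcript part at a probe. A gene was represented by the probe well above background on the most arrays, with ties going to the highest mean. Genes were counted at 2-fold among those well above background on both arrays compared, and those well above background on 1 of them were given as bounds. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the normalizations.

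The rule for named genes was fixed before the data were examined. It named PTH1R, KL, CYP27B1, CYP24A1 and VDR in any case. It then named the 8 largest differences each way (5 for high sodium against high phosphate) among genes with an approved-style symbol whose difference was over 2 times the spot error and had the same sign under each normalization. From each list it named up to 4 members at least 2-fold apart, or up to 2 of the largest otherwise, of which the report gives a selection, and it named the 3 largest bounds each way. Of the bounds, 1 is not reported here. Genes outside the rule are marked in the text as named after their values were seen. The 22 gene lists were also fixed before the data were examined: PTH, Klotho and vitamin D, vitamin D receptor targets, phosphate transport, sodium transport, hypertonic response, proximal tubule markers, markers of other kidney and blood cell types, epithelial-mesenchymal transition and fibrosis, tubular injury, NF-kappaB, interferon-stimulated genes, unfolded protein and amino acid responses, NRF2, heat shock proteins, cell cycle, p53 targets, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, calcification, and reference genes. The median of each list was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these arrays only. Some genes belong to more than 1 list.

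Of 10 spike-in probes, 9 were well above background and not saturated, and the SD over them of the log2 difference was 0.07 for high phosphate against normal, 0.10 for high sodium against normal and 0.14 for high sodium against high phosphate. The median SD over repeated spots of a probe was 0.03 on each array, but most repeated probes were bright. For the 15, 15 and 14 repeated probes below the 75th percentile on the normal, high phosphate and high sodium arrays, it was 0.20, 0.15 and 0.19. Unchanged arrays were simulated 100 times with Gaussian noise, its SD at each level taken from the difference between the treated arrays. That difference also holds any real difference between them.

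The counts and the list test were tested on simulated data with 26646 genes. For high sodium against normal, 98.0% of genes set 3-fold apart, 42.0% of those set 2-fold apart and 10.0% of those set 1.5-fold apart were counted, and 130 unchanged genes were counted too. Lists of 20 members with no shift lay outside the central 95% in 7.5% of cases, and lists shifted by 0.2 lay above it in 82.0%. Their members were drawn at random with independent noise, so these rates do not cover lists whose members vary together.

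Alternatives fixed before the data were examined were quantile normalization, scaling by the median, cyclic loess, scaling to spike-in probes, normexp background correction with an offset of 50, the series matrix values, no filter on dim probes, genes well above background on all 3 arrays, the mean over a gene's probes, all spots kept, and random lists not matched on expression. Scaling by the median or to spike-in probes shifts all genes of an array alike, so neither could change a list's place among random lists. The series matrix values are nearly those of the main processing. Counts of alternatives given for a list include these settings, which were no separate check of its place. The brighter genes, those above the median level, were added after the data were seen, as were the extra list of amino acid response genes, the split of the list of unfolded protein and amino acid responses, the comparison of the 2 probes of a gene and the tests in the closing section.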

Results

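Gene expression was measured in HK-2 cells, an established line of human proximal tubule cells of the kidney, that had been held quiescent in low serum and then kept for 24 h in normal, high phosphate or high sodium medium. Each medium was represented by 1 array, so the 3 comparisons had no replicate check, no p-values were computed, and the number of arrays limited the precision. All 3 arrays came from 1 slide and 1 scan, which left no batch to compare. The labels gave no concentrations. Of 58201 probes, 62.9% were well above background on the normal array, 62.7% on the high phosphate array and 63.4% on the high sodium array, and no spot outside the controls was saturated. The errors given with log2 differences are spot errors from the scanner software, which cover the measurement of the spot only. The software's multiplicative error was set at 0.1 on each array. Spot errors of brighter genes, near 0.20, followed from that setting and were not a measured spread. Differences are of log2 intensity relative to the 75th percentile of each array.

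The comparison of high sodium with normal addressed the question in the study's title, which named the parathyroid hormone receptor PTH1R, Klotho and active vitamin D. CYP24A1, the enzyme that breaks down active vitamin D, was 1.98-fold lower on the high sodium array, with a log2 difference of -0.99 and a spot error of 0.20. Its level was 1.53 on the normal array and 0.55 on the high sodium array, and its other probe also gave -0.99. VDR, the vitamin D receptor, was 1.35-fold lower, with levels of 0.92 and 0.49 and a difference of -0.43 with a spot error of 0.20. KL, the gene of Klotho, was 1.18-fold lower, with levels of 1.44 and 1.20 and a difference of -0.23 with a spot error of 0.20. PTH1R was 1.29-fold lower, at levels of -3.58 and -3.94, and its difference of -0.36 was within 2 spot errors of 0.28. CYP27B1, the enzyme that makes active vitamin D, differed by -0.20 with a spot error of 0.22, at levels of -2.50 and -2.70.

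Among the 1000 genes of like level, 0.1% had a lower difference than CYP24A1, 2.3% than VDR, 13.5% than KL, 18.2% than PTH1R and 23.4% than CYP27B1. Scaled to the spike-in probes, which put the median of all genes at 0.21, CYP24A1 differed by -0.78, VDR by -0.22, PTH1R by -0.15 and KL by -0.02, and the direction of CYP27B1 turned to 0.0080 above normal. After normexp background correction PTH1R differed by -0.08 and CYP27B1 by -0.05. On the hg19 build, the CYP24A1 probes lay on chromosome 20 at 52770946 to 52771005 and 52773929 to 52773988. The probe of VDR lay on chromosome 12 at 48235502 to 48235561, that of KL on chromosome 13 at 33639483 to 33639542 and that of CYP27B1 on chromosome 12 at 58156576 to 58156635. The PTH1R probe spanned 46944115 to 46944255 on chromosome 3.

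**Figure D1:**
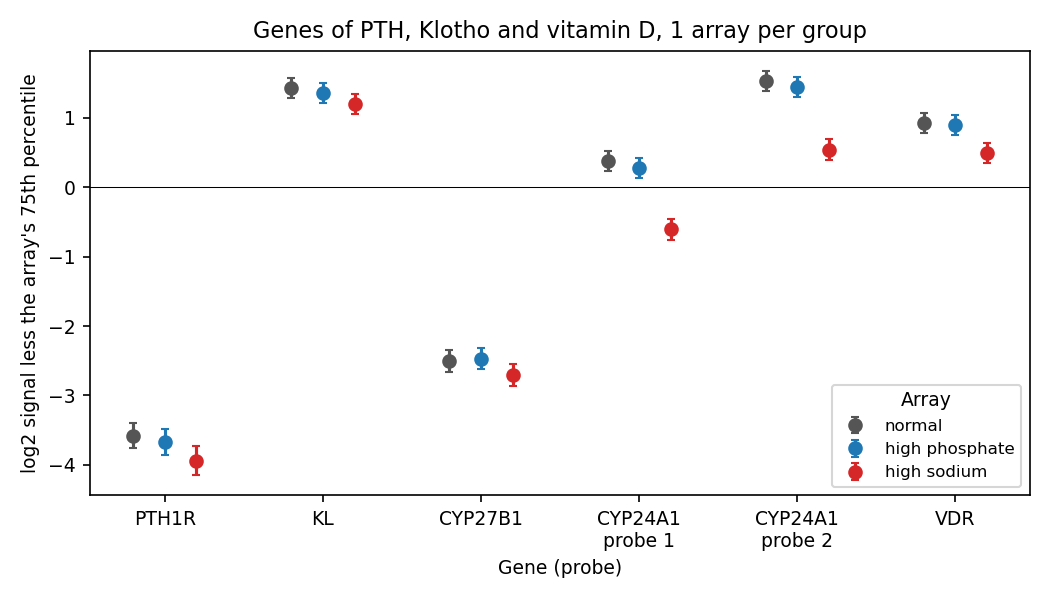
Level of PTH1R, KL, CYP27B1, CYP24A1 (both probes) and VDR on the normal, high phosphate and high sodium arrays, as log2 intensity relative to the 75th percentile of the array; each point is 1 array and bars show the spot error of the scanner software, not a spread between replicates. Both probes of CYP24A1 were lower on the high sodium array by 0.99, while PTH1R, KL and CYP27B1 differed by no more than the 0.36 of PTH1R, and under spike-in scaling the direction of CYP27B1 turned.

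Genes of the response to hypertonic medium were higher on the high sodium array as a group. Of 17 measured members of that list, 7 were higher and 2 lower by more than 2 spot errors, and the median of 0.15 lay at percentile 99.9 of 10000 random lists matched on expression. SLC6A12, the betaine transporter, was 2.01-fold higher with a spot error of 0.20 on the log2 scale. Further members were named after their values were seen. SLC5A3, the myo-inositol transporter, differed by 0.89, SLC6A6, the taurine transporter, by 0.64 and AKR1B1, aldose reductase, by 0.63. NFAT5, the transcription factor of the response to tonicity, differed by 0.37, while the amino acid transporter SLC7A5 differed by -0.80 and the urea transporter SLC14A2 by -0.61. In the list of sodium transport and its regulators, 17 of 22 members were above 0, and 3 were higher by more than 2 spot errors with none lower by as much. Its median of 0.15 lay at percentile 99.95. STK39, a kinase that regulates cation-chloride cotransporters, was 1.67-fold higher, and SLC12A3, the thiazide-sensitive cotransporter of sodium and chloride, differed by 0.52 with a spot error of 0.29. ATP1B1, a beta subunit of the sodium pump, differed by 0.44 and was also named after its value was seen.

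NF-kappaB and inflammatory genes were lower as a group, with 20 of 26 below 0, 11 lower by more than 2 spot errors and 2 higher. Their median of -0.20 was lower than in all 10000 random lists. The chemokine gene CXCL2 was 1.96-fold lower and its other probe gave -1.10, and TNFAIP3, an inhibitor of NF-kappaB signalling, was 1.73-fold lower. Named after their values were seen, CXCL3 differed by -0.74, CCL20 by -0.69, CXCL1 by -0.69 and CSF2 by -0.72, while IL1B differed by 0.52 and TNFAIP6 by 0.67. The list of unfolded protein and amino acid responses had 23 of 25 members below 0, 5 of them lower by more than 2 spot errors, and a median of -0.15 at percentile 0.01. ASNS, asparagine synthetase, was 1.68-fold lower and SLC7A11, the cystine transporter, 1.55-fold lower. In the list of NRF2 and oxidative stress genes, which also holds SLC7A11, 21 of 27 members were below 0, 3 were lower and 2 higher by more than 2 spot errors, and the median was -0.14 at percentile 0.05. HMOX1, heme oxygenase 1, was 1.46-fold lower, with a difference of -0.55. Interferon-stimulated genes had 16 of 24 members below 0 and a median of -0.11 at percentile 1.61, but only IFI27 differed by more than 2 spot errors, by 0.42, and it was higher. That list stayed outside the central 95% in 10 of 11 alternatives.

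Vitamin D receptor target genes had a median of 0.14 at percentile 98.42, with 9 of 15 members above 0, although 4 were lower and 2 higher by more than 2 spot errors. This list held CYP24A1, the largest difference in it, and KLK6, which was 1.73-fold higher, and its median stayed outside the central 95% of random lists in 7 of 11 alternatives. Relative to random lists the median was -0.0009 with no filter on dim probes. Immediate early genes had a median of 0.07 at percentile 97.56, with DUSP5 1.56-fold and DUSP1 1.45-fold higher, and stayed outside in 5 of 11 alternatives. Of these genes, 18 of 30 were above 0, and 4 were higher and 2 lower by more than 2 spot errors. The PTH, Klotho and vitamin D list had a median of -0.11 at percentile 3.94, with 3 of 16 members lower by more than 2 spot errors, among them CYP27A1 at -0.58. Scaled to the spike-in probes, this median turned to 0.10. It was 1 of 14 lists inside the central 95%, whose medians ranged from -0.11 to 0.07. Among these, oxidative phosphorylation had 29 of 33 members below 0 and a median of -0.07, against -0.03 for random lists of like level. The median of oxidative phosphorylation turned to 0.14 when scaled to the spike-in probes, and markers of other kidney and blood cell types had 8 of 15 above 0. Outside the central 95% lay 8 of 22 lists, where the nominal 5% would give 1.1. In simulated data 7.5% of random lists with no shift lay outside, but the noise there was independent between genes. That rate does not cover lists whose members vary together, and some of the lists share genes. Relative to the all-gene median of 0.21 under spike-in scaling, the lists that were below the others stayed below, but the direction from normal turned: the medians were 0.01 for NF-kappaB, 0.06 for unfolded protein and amino acid responses, 0.07 for NRF2 and 0.11 for interferon-stimulated genes, against 0.36 for both sodium transport and the hypertonic response.

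**Figure D2:**
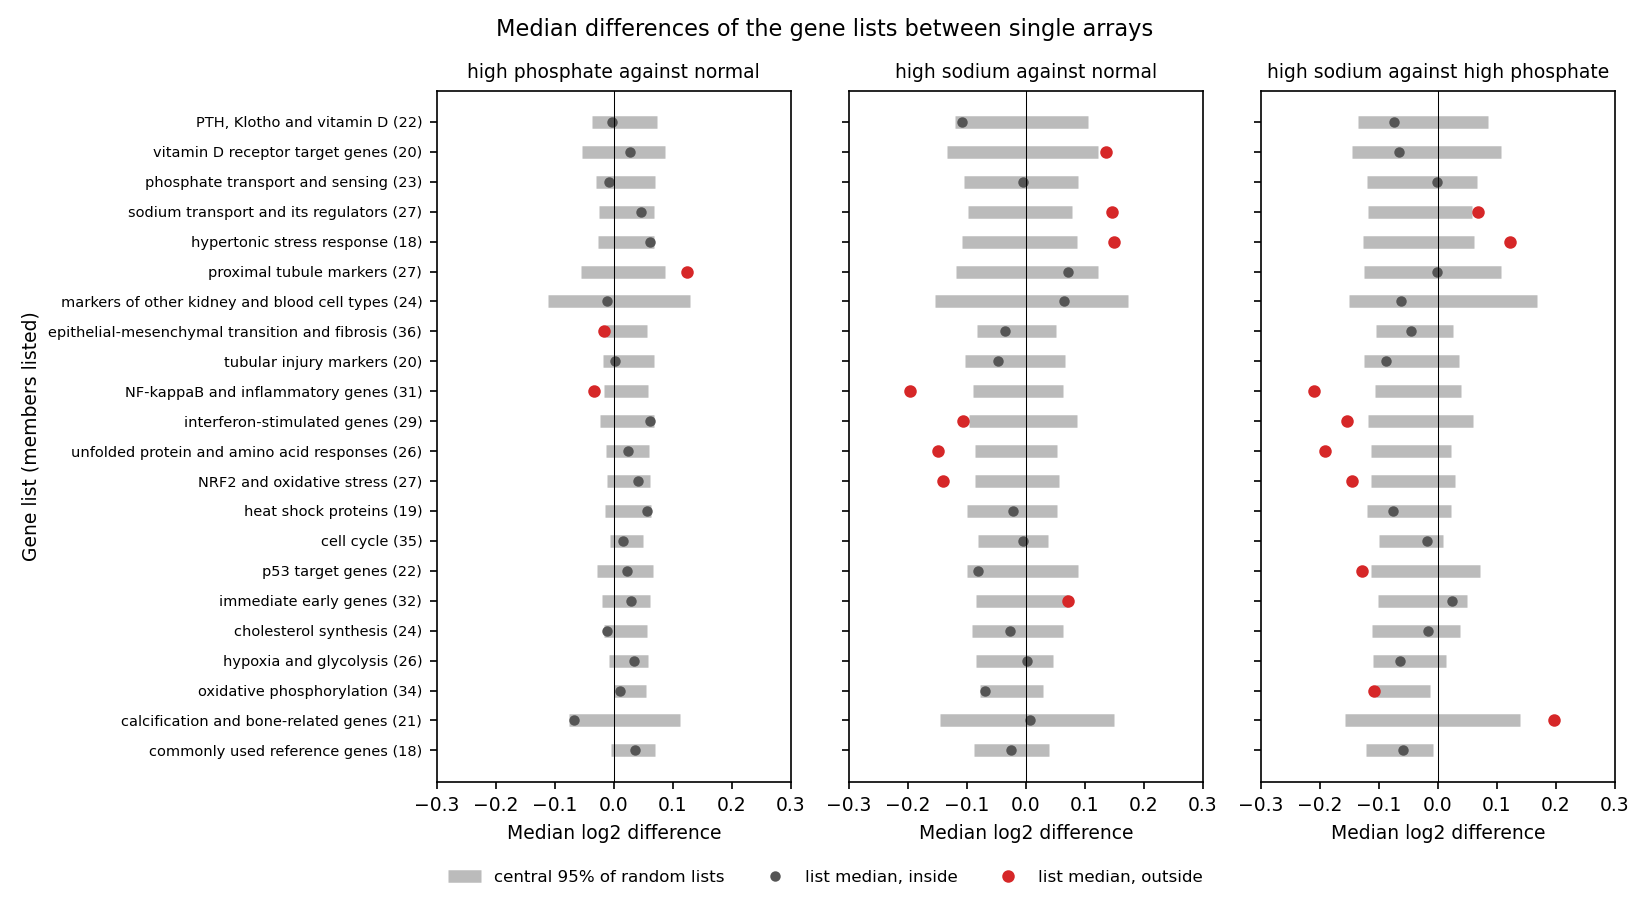
Median log2 difference of each of the 22 gene lists in the 3 comparisons (points), with the central 95% of 10000 random lists matched on expression (bars), for 1 array per group. In the comparison of high sodium with normal, the hypertonic response and sodium transport lists lie above their bars at 0.15, and NF-kappaB genes lie below at -0.20, a direction that turned to 0.01 above normal under spike-in scaling.

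Single genes with large differences were mostly dim. Of 27223 genes well above background on both arrays, 146 were at least 2-fold higher and 106 at least 2-fold lower on the high sodium array, which was 0.926% of them, and under spike-in scaling the split was 373 higher and 33 lower. Among genes with an approved-style symbol that met the naming rule, the largest higher differences were those of RCAN2, a regulator of calcineurin (4.09-fold), SIRPB2 (3.89-fold), the imprinted gene PEG3 (3.51-fold) and PRSS35 (3.38-fold). Next came DDIT4L, an inhibitor of mTOR signalling (3.36-fold), TMED9 (3.15-fold), the nucleoside transporter SLC29A2 (3.10-fold) and KILH (2.89-fold). Lower by the most among such genes were ERP27, a protein of the endoplasmic reticulum (9.06-fold), PNCK (3.33-fold), HS3ST6 (3.02-fold) and the pseudogene KATNBL1P6 (a log2 difference of -1.59). These were followed by the pseudogene CLEC4GP1 (2.83-fold), the stress response gene GADD45G (2.74-fold), LRRC37A8P (2.69-fold) and the peroxidase GPX7 (2.60-fold), and the spot errors of these 8 genes each way were 0.20 to 0.35. Only TMED9, DDIT4L, PRSS35, GADD45G and ERP27 among them stayed at least 2-fold apart after normexp background correction, ERP27 at -1.11. SIRPB2, PEG3, TMED9, SLC29A2, KILH, ERP27, PNCK, KATNBL1P6 and CLEC4GP1 were also at least 2-fold apart the same way on the high phosphate array. Both differences of these genes were taken from the single normal array and may rest on it. RCAN2 had another probe well above background that gave -1.19, and that of KILH gave 0.01. Both probes were at least 2-fold apart the same way for 3 of the 17 such genes with another probe well above background. They were DDIT4L with 1.75 and 1.85, GADD45G with -1.46 and -1.18, and MIR205HG, named after its values were seen, with 1.12 and 1.07. The DDIT4L probe lay on chromosome 4 at 101107080 to 101107139 and that of GADD45G on chromosome 9 at 92221400 to 92221459.

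Genes well above background on only 1 of these arrays gave bounds, with 1170 on the high sodium array only and 939 on the normal array only. TPSAB1, a mast cell tryptase, was at least 24.5-fold lower, SNX20 at least 5.57-fold lower and TRIM77 at least 3.22-fold lower. TPSAB1 and SNX20 were not well above background on the high phosphate array either, so their bounds rest on the single normal array. In the other direction, CDRT8 was at least 3.23-fold, LDLRAD4 at least 2.72-fold and the cholesterol exporter ABCG1 at least 2.67-fold higher. The count of genes at least 2-fold apart rested on dim probes: 12 were higher and 7 lower among the 14888 brighter genes, 11 were higher and 4 lower after normexp background correction, and 1543 were higher and 1395 lower with no filter. Across 1358 genes in the brightest quartile of those with 2 probes, the differences of the 2 probes had a Pearson r of 0.64, against 0.32 over all 5432 such genes.

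**Figure D3:**
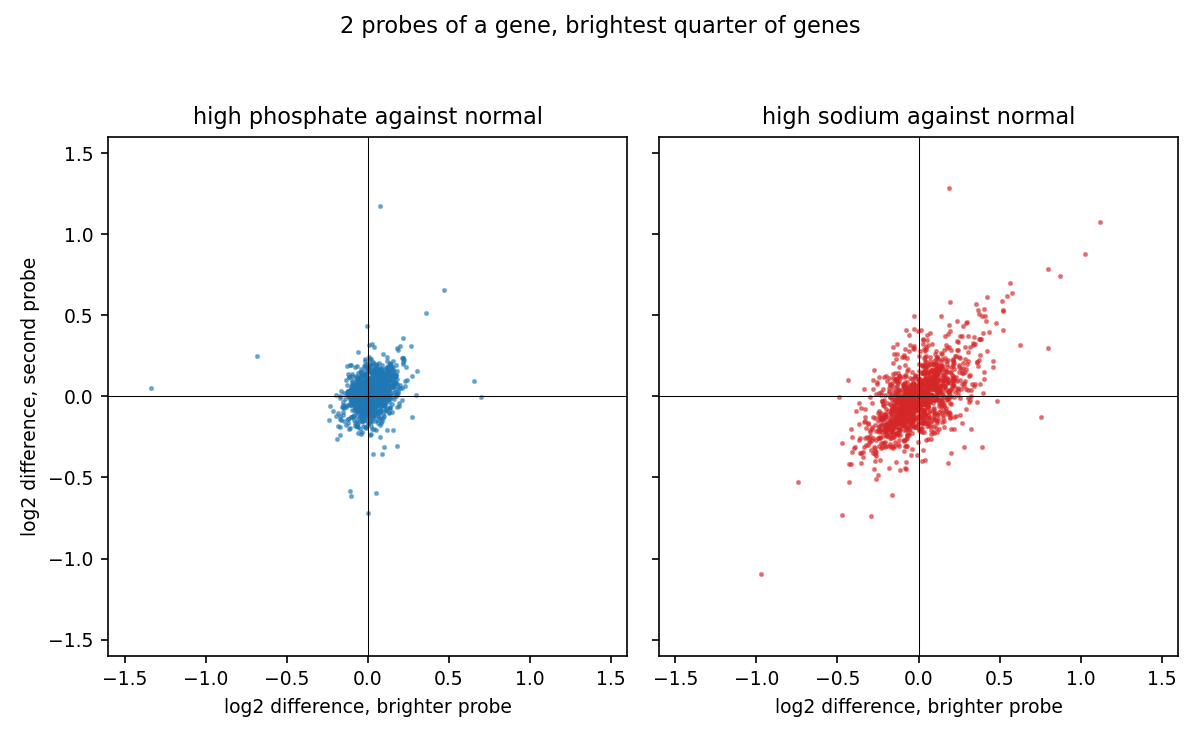
Log2 difference from normal at 1 probe of a gene (horizontal axis) against that at its other probe (vertical axis), for the high phosphate array and the high sodium array; each point is 1 of the 1358 genes in the brightest quartile of genes with 2 probes. The points of high sodium follow the diagonal with an r of 0.64, and those of high phosphate gather near 0 with an r of 0.25.

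High phosphate was compared with normal as the other treatment in the design. Proximal tubule markers had 14 of 20 members above 0 and a median of 0.12 at percentile 99.73, although 1 was higher and 1 lower by more than 2 spot errors. Relative to random lists that median was 0.0659 after normexp background correction and 0.0401 with the mean over a gene's probes, and the list stayed above the central 95% in 10 of 11 alternatives, with a lowest percentile of 85.03. The organic cation transporter SLC22A2 differed by 0.68 with a spot error of 0.34, and the aminopeptidase ANPEP by -0.70 with a spot error of 0.32. NF-kappaB and inflammatory genes had a median of -0.03 at percentile 0.35, with 14 of 26 members below 0, and stayed outside the central 95% in 10 of 11 alternatives. IL1B was 1.55-fold higher. Genes of epithelial-mesenchymal transition and fibrosis had a median of -0.02 at percentile 1.59, with 18 of 31 below 0 and none beyond 2 spot errors, and stayed outside the central 95% in 7 of 11 alternatives. The other 19 lists lay inside, with medians from -0.07 to 0.06. Phosphate transport and sensing genes were among them, with 9 members above 0 and 12 below 0 and a median of -0.0082. So were the calcification and bone-related genes, with a median of -0.07 at percentile 3.45 and the transcription factor MSX2 at -0.61. Among the genes of the title's question, PTH1R differed by -0.10, KL by -0.08, CYP24A1 by -0.08, VDR by -0.02 and CYP27B1 by 0.03, all within their spot errors, and spike-in scaling turned CYP27B1 to -0.03, while normexp background correction turned PTH1R to 0.05 and put CYP27B1 at 0.13.

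Of 27079 genes well above background on both arrays, 110 were at least 2-fold higher and 164 at least 2-fold lower on the high phosphate array, which was 1.01% of them. Of genes with an approved-style symbol that met the naming rule, the largest higher differences belonged to TAF15, an RNA-binding protein (5.25-fold), SIRPB2 (a log2 difference of 2.32) and FXYD4, a regulator of the sodium pump (4.68-fold). They were followed by TMED9, a cargo receptor of the early secretory pathway (4.60-fold), APELA, a ligand of the apelin receptor (3.59-fold), KILH (3.39-fold), the tight junction gene CLDN14 (3.14-fold) and SLC29A2 (2.83-fold), with spot errors of the named genes from 0.20 to 0.34. ERP27 (6.40-fold), the beta-defensin DEFB121 (3.15-fold), ZMAT4 (3.02-fold) and SOWAHD (2.93-fold) were lower by the most among such genes. Next were the matrix proteoglycan ASPN (2.93-fold), UTP14C (2.82-fold), PNCK (2.80-fold) and CCDST (2.78-fold). Of these 8 genes each way, only TAF15, TMED9, APELA, KILH, SOWAHD and UTP14C stayed at least 2-fold apart after normexp background correction. TAF15, SIRPB2, TMED9, APELA, KILH, CLDN14, SLC29A2, ERP27 and PNCK were also at least 2-fold apart the same way on the high sodium array. Their differences may therefore rest on the single normal array. Another probe well above background gave -0.56 for KILH, 0.13 for UTP14C and -0.27 for CCDST. In the fixed lists, only SLC4A1 was at least 2-fold apart, at -1.31, and its other probe gave 0.17. Bounds were at least 3.43-fold higher for ABCG1 and 2.98-fold for LOHAN2. They were at least 23.0-fold lower for TPSAB1, 5.23-fold for SNX20 and 4.66-fold for LRRC37A8P, out of 1019 genes seen on the high phosphate array only and 1080 on the normal array only. TPSAB1 and SNX20 were also bounds for high sodium against normal, and rest on the single normal array.

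No gene was at least 2-fold apart on both of its probes in this comparison, out of 20 such genes with another probe well above background, and 11 of the 20 had the same sign on that probe. Differences of the 2 probes of a gene had an r of 0.07 over all genes and 0.25 in the brightest quartile. The SD of the differences over genes was 0.42 in the dimmest quartile of genes and 0.10 in the brightest, against 0.43 and 0.18 for high sodium. The counts again rested on dim probes, with 11 higher and 18 lower among the brighter genes, 11 higher and 13 lower after normexp background correction and 1341 higher and 1713 lower with no filter.

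High sodium was also compared with high phosphate, which set the treated arrays against each other. Calcification and bone-related genes were higher on the high sodium array than on the high phosphate array, with 10 of 15 members above 0, 2 of them by more than 2 spot errors, and a median of 0.20 at percentile 99.58. Against normal, the median of this list was 0.0064 at percentile 53.29 for high sodium and -0.07 for high phosphate. MSX2 was 1.52-fold higher and RUNX2, a transcription factor of bone formation, 1.44-fold higher, but the other probe of RUNX2 gave 0.0005. Relative to random lists the median of this list was 0.0931 after normexp background correction. The hypertonic response list had a median of 0.12 at percentile 99.92, with SLC5A3 1.81-fold and SLC6A12 1.72-fold higher. Sodium transport had a median of 0.07 at percentile 98.51, with STK39 1.54-fold higher. Sodium transport, the hypertonic response, calcification, p53 targets and oxidative phosphorylation each came inside the central 95% in 1 of 11 alternatives, sodium transport at percentile 92.17. Medians were below those of the other genes for NF-kappaB (-0.21, lower than in all 10000 random lists), unfolded protein and amino acid responses (-0.19 at percentile 0.01), NRF2 (-0.15 at 0.18), interferon-stimulated genes (-0.15 at 0.31), p53 targets (-0.13 at 1.12) and oxidative phosphorylation (-0.11 at 1.56). CXCL2 was 1.72-fold, ASNS 1.41-fold, HMOX1 1.37-fold and the interferon-stimulated gene IFI44L 1.48-fold lower, while TNFAIP6 was 1.83-fold higher. In the NRF2 list GCLM was higher by 0.44, and 1 member was higher and 4 lower by more than 2 spot errors. The p53 target TP53I3 was 1.52-fold lower with -0.51 at its other probe, while TIGAR, the largest difference of that list, was higher by 0.97. Of the p53 targets, 1 was higher and 2 lower by more than 2 spot errors. Of the oxidative phosphorylation genes, 31 of 33 were below 0. Random lists of like level were below 0 too, with a median of -0.06 and a central 95% of -0.10 to -0.01. The other 13 lists lay inside the central 95%, with medians from -0.09 to 0.02. SLC4A1 was the only list member at least 2-fold apart, at 1.43 with -0.08 at its other probe. Spike-in scaling put the median of all genes at 0.25 and turned the direction of the lower lists, to 0.06 for NF-kappaB, 0.08 for unfolded protein and amino acid responses, 0.12 for NRF2, 0.11 for interferon-stimulated genes, 0.14 for p53 targets and 0.16 for oxidative phosphorylation, all below that median.

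CYP24A1 was 1.87-fold lower on the high sodium array than on the high phosphate array, with -0.89 at its other probe, and VDR was 1.33-fold lower. PTH1R differed by -0.26 with a spot error of 0.28, KL by -0.15 with 0.20 and CYP27B1 by -0.23 with 0.22, and under spike-in scaling these directions turned, to 0.0033 for PTH1R, 0.11 for KL and 0.03 for CYP27B1. Normexp background correction put PTH1R at -0.13. Of 27244 genes, 144 were at least 2-fold higher and 93 at least 2-fold lower, against 465 and 20 under spike-in scaling. By the naming rule, which takes approved-style symbols only, the 5 largest higher differences were those of ACTL9 (3.35-fold), SOWAHD (3.33-fold), ZNF621 (3.04-fold, with 0.03 at its other probe), GCSAM (2.95-fold) and the proprotein convertase PCSK4 (2.93-fold). The 5 lower by the most under that rule were the peroxisomal oxidase ACOX2 (2.66-fold), GADD45G (2.63-fold, with -1.20 at its other probe), LRRC32 (2.61-fold), C2CD4A (2.48-fold) and the phospholipase GPLD1 (2.48-fold), and spot errors of these genes were 0.20 to 0.36. SOWAHD, ZNF621, PCSK4 and GADD45G stayed at least 2-fold apart after normexp background correction, and the others did not. Bounds were at least 2.91-fold higher for MFSD2B, 2.59-fold for SNHG22 and 2.58-fold for TGM7. They were at least 5.73-fold lower for FXYD4, 2.53-fold for the necroptosis kinase RIPK3 and 2.53-fold for RNF125. Both probes were at least 2-fold apart the same way for 3 of 18 genes with another probe, again DDIT4L, GADD45G and MIR205HG. Among brighter genes 13 were higher and 9 lower, normexp background correction gave 11 and 5, and no filter gave 1647 and 1208.

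The differences of high phosphate and of high sodium from normal shared the normal array, which correlates them without any treatment. Across 26646 genes well above background on all 3 arrays, their Pearson r was 0.46, their Spearman rho 0.39 and their covariance 0.0373, against 0.50, 0.47 and 0.0431 in 100 simulations of unchanged arrays that shared 1 control. Among brighter genes r was 0.32 and the covariance 0.0089, against 0.50 and 0.0217. The simulated r of 0.50 followed from equal noise on arrays that share 1 control, whatever the data. The simulated noise came from the difference between the treated arrays, with an SD of 0.17 in the brightest quartile. For high phosphate against normal that SD was 0.10. Values below the simulated ones therefore decide nothing about an effect common to both media. At least 2-fold higher on both treated arrays were 51 genes, among them TAF15, TMED9 and SIRPB2, of 109 for high phosphate and 144 for high sodium. Of the 51, only TAF15 and TMED9 were among the brighter genes. For this overlap, independent draws would give 0.589 and the simulations gave a mean of 7.79 and a range of 2 to 15. At least 2-fold lower on both were 17 genes, among them ERP27, of 158 and 98, where independent draws would give 0.581 and the simulations a mean of 8.65 and a range of 1 to 17. A single control array cannot be split between the comparisons, so part of this overlap can come from that array.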

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

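The alternative restricted to brighter genes was chosen after the data were seen; all others were planned. No value was labelled reversed, but that label was possible only for main values of at least 1 in size. No list median, gene of the title's question or correlation reached 1, and counts could not get the label. For these, the absence of reversals shows nothing. Of 66 list medians taken relative to random lists, 18 of 726 values moved and 26 changed sign; of the named genes, 159 of 1628 moved and 7 changed sign; and of the genes of the title's question, 7 of 150 moved and 6 changed sign, all in differences of less than 2-fold. The cause was not tested, except that no filter and brighter genes by construction count other genes. No paired analysis was possible because each group had 1 array and the groups share only the replicate number 1, and no array could be left out. Signal over background limits the counts. Counts at least 2-fold higher and lower for high phosphate against normal were 11 and 13 with normexp, 1341 and 1713 with no filter, and 11 and 18 among brighter genes. For high sodium against normal they were 373 and 33 with spike-in scaling, 11 and 4 with normexp, 1543 and 1395 with no filter, and 12 and 7 among brighter genes. For high sodium against high phosphate they were 465 and 20, 11 and 5, 1647 and 1208, and 13 and 9. Spike-in scaling gave for high sodium against normal KL -0.0209, CYP24A1 -0.78 and VDR -0.22, and against high phosphate KL 0.11, CYP27B1 0.0336, CYP24A1 -0.64 and VDR -0.14. The correlation of the differences from normal was 0.32 among brighter genes. List medians relative to random lists, for high phosphate against normal, were with the mean over probes 0.0177 (hypertonic response), 0.0401 (proximal tubule) and -0.0374 (calcification), with normexp 0.0659 (proximal tubule) and -0.0227 (cell cycle), with quantile normalization 0.0112 (heat shock) and 0.0312 (immediate early), and with no filter -0.0166 (calcification). For high sodium against normal they were -0.0009 with no filter and 0.0686 with the mean over probes (vitamin D receptor targets), and -0.0361 and -0.0589 (other cell types). For high sodium against high phosphate they were, with lists not matched on expression, -0.0594 (heat shock), -0.0017 (cell cycle), -0.0467 (hypoxia), -0.0919 (oxidative phosphorylation) and -0.0436 (reference genes), and with normexp 0.0931 (calcification). For high sodium against normal, the lists of sodium transport, hypertonic response, NF-kappaB, unfolded protein and NRF2 stayed outside the central 95% on the same side in 11 of 11 alternatives. Scaling by the median and to spike-in probes could not change these places, and the series matrix values were nearly the same. Those alternatives therefore add nothing to that count.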

Other observations

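The tests of probe noise, of intensity trends and of the shared 2-fold genes were chosen after the results were seen, and those of RNA length, single cultures, the amino acid response and the chaperones were written before theirs. Among the brighter genes, which were chosen after their values were seen, the high sodium array had higher levels of MAL, a membrane protein of apical sorting (1.15), FNDC11 (1.15), PCDH1 (1.09, but -0.12 at its other probe), BCAS1 (1.05 and 0.75 at its other probe), the long noncoding RNA UCA1 (1.02 and 0.88) and the integrin ITGB8 (1.01), as log2 differences from normal. Lower there were CDHR3 (-1.16, but -0.10 and 0.04 at its other probes), the protease inhibitor SLPI (-1.12), TPPP3 (-1.09), the collagenase MMP1 (1.99-fold lower) and IL4I1 (-0.93). MRPS6, whose locus overlaps that of SLC5A3, differed by 0.70, beside 0.89 for SLC5A3.

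The differences of the high sodium array from normal agreed between probes of the same gene. For probes at least 200 bases apart, in the brightest quartile of genes, r was 0.60, against 0.21 for high phosphate, which argues against noise of single spots or probes. A trend with intensity is argued against: the median difference of probes of like level, read at both probes, had 0.18% of the covariance of the differences. Shortening of RNA alike in most genes of the high sodium sample is argued against as the whole cause. The median excess of the 3 prime probe was 0.0427, just inside the bound of 0.05 set beforehand. Its resampled range of 0.0347 to 0.0499 lies above 0, in the direction of shorter RNA, and high phosphate gave 0.0166. A median cannot decide on shortening that differs between genes. The interquartile range of the excess over genes was 0.30 for high sodium and 0.23 for high phosphate. A difference between single cultures unrelated to sodium cannot be told apart from an effect of sodium, since there was 1 array per group, and that effect stays a hypothesis.

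Of the genes at least 2-fold higher than normal on both treated arrays, the 51 found exceeded the highest of the simulations, 15. This argues only against Gaussian scatter of the simulated size. The noise came from the difference between the treated arrays, so it held no outlying probes of the normal array. The simulations therefore cannot decide on chance scatter of such probes. The 17 genes lower on both equalled the highest of the simulations, 17, whose mean was 8.65. That number lay within their range only at its edge. With the same limit on the simulated noise, the simulations do not decide on chance scatter for these genes either. A departure of single probes on the normal array stays open: 0 of 3 genes with another probe well above background showed the difference there, too few to decide. An effect common to both media was not tested otherwise.

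The lower list of unfolded protein and amino acid responses on the high sodium array lay below all genes by a distance of which a trend with intensity, read at the levels of its members, gave 9.34%, which argues against that trend as the whole cause. Genes of the amino acid response outside the fixed lists had a median of -0.11 at percentile 0.91, with 20 of 24 below 0. A lower amino acid response relative to other genes is consistent with this value, as a hypothesis tested on the same arrays, but scaled to the spike-in probes, which put all genes at 0.21, the median turned to 0.10 above normal. The chaperones and XBP1 targets of the list had -0.16, but as members of the list that showed the pattern they decide nothing about lower endoplasmic reticulum chaperones, which stays open. For high phosphate against normal, the amino acid genes outside the lists had -0.0175 at percentile 2.84, with 13 of 24 below 0, just inside the random lists. For high sodium against high phosphate they had -0.07 at percentile 17.19, also inside. The low value against normal may therefore rest in part on the single normal array. With 1 array per group a difference between single cultures stays open too.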
